A study of Homo sapiens with 7 samples.

How the data were processed

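Lysates of fixed and sonicated HT1080 nuclei were immunoprecipitated with antibodies against phosphorylated H2A, ubiquitylated H2A or VRK1, and per the labels' protocols the libraries went through 20 cycles of PCR and 36 cycles of sequencing on a Genome Analyzer. There were 7 libraries, 1 per antibody or input DNA and siRNA. Groups were taken from the sample titles. The submitters' processing notes name CASAVA 1.8.2, Bowtie 0.12.8, Partek and the genome build hg19, without the role of each. Per the file headers the reads were aligned to hg19, and peaks were called by library, each list holding the peaks of 1 library. The peak-calling settings, the treatment of duplicate reads and any use of the input as control are not given in the sources used here. Short reads and 20 PCR cycles leave repeated sequence and PCR duplicates as sources of high counts, and several very high regions lay near centromeres.

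The deposited lists give, for every peak, its position and its length in bp. The peak height is a signal per the file headers: the highest number of extended reads in a window of the peak, in the library in which it was called. The same height was deposited as RPM, scaled to the total reads of the library, and height divided by RPM gave each library total. The authors' caller also gave a Mann-Whitney p-value per peak, which was used only to describe the lists. Per the file headers, each list holds the count of reads of all 7 libraries in each of its regions, not normalized. The percent of each region covered by the peaks of each other library was also deposited and served to check overlaps. Heights are the authors' own values and were used to rank and filter peaks within a list. Extended reads set the peak bounds, so the count in a region can lie below its height: this held for 25.9% to 36.9% of the peaks of a library, and for 0.495% or less the count was below 0.5 of the height.

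Positions are those of the files, in hg19; whether they count from 0 or 1 is not given in the sources used here. The lists carry no gene names. The only annotation at hand was of another build, and positions were not converted between builds. Promoter peaks, gene lists and the CCND1 and VRK1 loci, all planned before the data were examined, are therefore not analysed here, and peaks are named by position.

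The rule for named peaks was written before the data were examined, for genes, and names peaks by position where genes cannot be named. Its limit of 4 was meant for members of gene lists. Taking those 4 from all peaks outside input peaks was an adaptation. As used here, the rule takes, for each antibody library, the 5 highest peaks that overlap no peak of either input. It adds the 4 highest peaks found under only 1 siRNA for pT120 and for ubK119, and the 6 highest VRK1 peaks that also overlap a pT120 peak, again outside input peaks. The chromosome windows, the longest ubK119 peaks, the stretch on chromosome 1 that resembles mitochondrial DNA and the region near the centromere of chromosome 8 were chosen after their values were seen. A named peak is given as the longest region that any antibody library had there, so that its count is complete.

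Overlap meant at least 1 bp. It was set beside 1000 circular shifts of the first list within each chromosome, which was the planned chance level. Where DNA copies are amplified, such shifts give too low a level, and moves of each peak by 5 to 50 kb (100 draws) were added after the data were seen. Peak numbers of the siRNA pairs were also compared after binomial thinning of the heights of the deeper library to the total of the other (20 draws), with the higher of the height minimums for both. RPM in regions called in a library other than those compared were summed over regions with at most 100 reads in each input, and the ratio of siVRK1 to siControl was given with an exact conditional binomial 95% interval. Where regions of both inputs were pooled, the longest of overlapping regions was used. Shares have exact Clopper-Pearson 95% intervals. These read comparisons were chosen after the columns of the lists were seen. No p-value was computed, since regions are not replicates and there was 1 library per condition. A level of 3 reads in a region corresponded to 0.0742 to 0.145 RPM.

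The overlap calls were checked against the deposited percent of coverage and differed in 0 cases. The ratio was tested on simulated data, with pT120 reads drawn for the 16870 regions called with the VRK1 antibody. True ratios of 0.5, 1 and 1.5 came out as 0.5001, 0.9998 and 1.5001, with intervals that held the true value in 94.5%, 95% and 94.5% of draws. The simulated reads had counting error only, as the interval assumes, so this checks the calculation and not the spread of the real reads. Thinning of simulated windows gave 1.0043 times the number of windows at the lower depth. Each simulated window had an independent count, whereas a deposited height is the highest within a peak. The simulation therefore does not show whether thinning such heights gives too few peaks. Alternatives concerned the overlap minimum, the peak height, input peaks, list length, the chance level, depth, the scaling of reads and chromosomes left out. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.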

Results

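Chromatin of HT1080 cells, a human fibrosarcoma line, was profiled by immunoprecipitation and sequencing after transfection of small interfering RNA against the kinase VRK1 (siVRK1) or of a non-targeting RNA (siControl). The antibodies recognised histone H2A phosphorylated at the threonine T120 (pT120), H2A ubiquitylated at the lysine K119 (ubK119, a mark placed by Polycomb complexes) and VRK1 itself. The marks and the input DNA were profiled under both siRNAs, and VRK1 in siControl cells, which gave 7 libraries. The library totals were 20687408 reads for siControl pT120, 36030842 for siVRK1 pT120, 32040499 for siControl VRK1, 40442635 for siControl ubK119 and 29976119 for siVRK1 ubK119. The siControl and siVRK1 inputs had 26893399 and 33259276 reads. VRK1 was profiled in siControl cells only, so the depletion of VRK1 by siVRK1 is not verified here. With 1 library per condition, no difference has a replicate check, and each comparison is one of libraries rather than of conditions. All intervals are 95% intervals of counting error only, since PCR reads without molecular identifiers are not independent molecules. Where intervals under both siRNAs are said to overlap, this does not show that the levels are equal.

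The first question was where each antibody gave peaks beyond those of input DNA. Peaks were short in every library, with median lengths from 218 to 254 bp, and many regions were also called in unprecipitated DNA. In siControl cells 17531 VRK1 peaks covered 5.93 Mb, 6665 pT120 peaks covered 2.34 Mb and 28955 ubK119 peaks covered 8.99 Mb. After siVRK1, 42461 pT120 peaks covered 12.3 Mb and 13818 ubK119 peaks covered 4.81 Mb. The siControl and siVRK1 inputs themselves had 17980 and 21507 peaks. Of the siControl pT120 peaks, 44.5% (43.3 to 45.7) overlapped a peak of the siControl input, against 23.7% (23.1 to 24.3) of VRK1 peaks and 13.8% (13.4 to 14.2) of ubK119 peaks. After siVRK1 the share with a peak of the siVRK1 input was 8.52% (8.25 to 8.79) for pT120 and 26.6% (25.8 to 27.3) for ubK119. Circular shifts gave 0.926% for siControl pT120 and between 0.684% and 0.766% for the other antibody libraries. Moves of 5 to 50 kb gave 20.5% for siControl pT120, 10.8% for VRK1, 7.52% for siControl ubK119, 6.09% for siVRK1 pT120 and 9.72% for siVRK1 ubK119. Peaks outside both inputs numbered 3050 and 37994 for siControl and siVRK1 pT120, 23695 and 9814 for siControl and siVRK1 ubK119, and 11489 for VRK1. The lists were drawn up with height minimums between 12 and 18 reads and at different depths, so their numbers are not directly comparable.

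The comparison of pT120 between siControl and siVRK1 cells asks where the mark differed after siVRK1. At the 16870 regions called with the VRK1 antibody, the level of pT120 was 6622 RPM in siControl and 3718 RPM in siVRK1 cells, a ratio of 0.562 (0.557 to 0.566). Ratios lay below 1 on 24 of 24 chromosomes, from 0.403 (0.385 to 0.421) on chromosome 17 to 0.980 (0.916 to 1.05) on chromosome X, where the interval includes 1. At regions called with the ubK119 antibody, the pT120 ratio was 0.478 (0.474 to 0.482) for the siVRK1 list and 0.847 (0.842 to 0.853) for the siControl list. Regions called in input DNA had a pT120 ratio of 0.609 (0.605 to 0.612), and the 11489 VRK1 regions outside input peaks had 0.463 (0.457 to 0.469). Relative to the input regions, the ratio was 0.922 at VRK1 regions, 0.785 at siVRK1 ubK119 regions and 1.39 at siControl ubK119 regions, which turns the direction for the last. Outside input peaks, regions without a VRK1 peak had a pT120 ratio of 0.378 (0.373 to 0.384) for the siVRK1 ubK119 list and 0.901 (0.893 to 0.909) for the siControl list. In the VRK1 peaks outside input peaks, pT120 stood at 1.20 times (1.18 to 1.21) the siControl input, and after siVRK1 at 0.469 times (0.464 to 0.474) the siVRK1 input. The size of the siControl excess depended on the input used: 2715 RPM stood against 2270 RPM in the siControl and 2682 RPM in the siVRK1 input. The siVRK1 level of 1257 RPM lay below both inputs.

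The numbers of pT120 peaks went the other way, with 6.37 times as many after siVRK1 as in siControl cells. Both lists had a minimum of 12 reads, while the siVRK1 library was deeper. Thinned to the siControl depth, the siVRK1 library had 2325 peaks (2278 to 2375 over draws) against 6665, a ratio of 0.349, and outside input peaks 690 against 3050. The median height of the siVRK1 peaks was itself 12 reads, so thinning favoured this fall. Of the 6665 siControl peaks, 2620 overlapped a siVRK1 peak (39.3%, 38.1 to 40.5), 4045 were found in siControl cells only, and 40011 siVRK1 peaks had no siControl partner. Circular shifts gave 1.69% and moves of 5 to 50 kb gave 23.7%. Outside input peaks the share was 3.87%, or 118 of 3050 peaks.

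A choice among pT120 peaks found under 1 siRNA only favours a lower level under the other siRNA. No direction is therefore drawn from the ratios of such peaks. The highest pT120 peaks found in siControl cells only, outside input peaks, lay on chromosomes 3, 1, 14 and 5. On chromosome 3 (84163786 to 84164138), 27 reads in siControl stood against 10 in siVRK1 cells, an RPM ratio of 0.213 (0.0918 to 0.453). On chromosome 1 (160951061 to 160951454), 23 reads stood against 3, a ratio of 0.0749 (0.0144 to 0.248). On chromosome 14 (45221476 to 45221790) the ratio was 0.313 (0.141 to 0.661). These ratios are not scaled to the inputs, which had 4 and 0 reads, 4 and 7 reads, and 8 and 3 reads in the 3 regions. Over its own input, pT120 on chromosome 1 stood at 7.47 (2.55 to 29.7) and 0.396 (0.066 to 1.73) times, and on chromosome 14 at 3.57 (1.53 to 9.29) and 3.69 (0.996 to 20.4) times, so the lower level on chromosome 14 was not found relative to input. On chromosome 3 it stood at 8.77 (3.06 to 34.5) times in siControl cells, and with 0 input reads after siVRK1 no lower level relative to input is shown there. The region on chromosome 5 (138347033 to 138347233) was listed with a height of 22 reads but a count of 1 read, and no ratio is drawn from it. Among the highest peaks found after siVRK1 only, a pair lay close to the end of chromosome 4. The region from 190194833 to 190195314 had 13 and 62 reads, a ratio of 2.74 (1.49 to 5.43), and that from 190883320 to 190884133 had 14 and 64 reads, a ratio of 2.62 (1.46 to 5.07). The others were on chromosome 1 (5734986 to 5735664), with a ratio of 1.63 whose interval (0.952 to 2.92) includes 1, and on chromosome Y (59014240 to 59014721), with a ratio of 2.19 (1.11 to 4.72). Over its own input, pT120 stood at 1.21 (0.522 to 2.77) and 4.40 (2.396 to 8.73) times in the first region of chromosome 4, 1.82 (0.752 to 4.58) and 3.48 (2.01 to 6.33) times in the other, and 1.19 (0.476 to 2.95) and 2.58 (1.40 to 5.02) times on chromosome Y, with overlapping intervals each time.

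**Figure D1:**
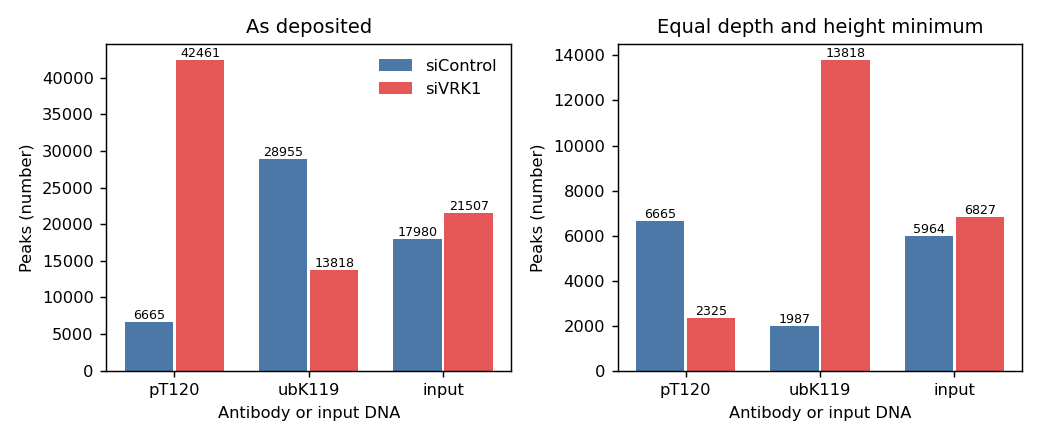
Number of peaks per library for pT120, ubK119 and input DNA in siControl (blue) and siVRK1 (red) cells, as deposited (left) and after thinning to equal depth with an equal height minimum (right); each bar is 1 library. For pT120 the order of the bars turns from 6665 and 42461 to 6665 and 2325, and for ubK119 from 28955 and 13818 to 1987 and 13818. Only the deeper library of each pair was thinned, which favours a fall in that library.

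The same comparison for ubK119 asks whether the ubiquitin mark differed after siVRK1. At the regions called with the VRK1 antibody, ubK119 was 5034 RPM in siControl and 7850 RPM in siVRK1 cells, a ratio of 1.56 (1.55 to 1.57). The ratio was below 1 on 0 of 24 chromosomes and ranged from 1.21 (1.14 to 1.29) on chromosome X to 1.82 (1.76 to 1.88) on chromosome 17. Chromosome 17 thus had the lowest pT120 ratio and the highest ubK119 ratio, and chromosome X the reverse. The input ratio was also highest on chromosome 17, at 1.38 (1.33 to 1.43), and on chromosome X it was 0.890 (0.834 to 0.949). At siControl pT120 regions the ubK119 ratio was 1.51 (1.495 to 1.52), and at regions called in input DNA 1.47 (1.46 to 1.48). Relative to these input regions, the ratio at VRK1 regions was 1.06. Outside input peaks the VRK1 regions had a ubK119 ratio of 1.71 (1.698 to 1.73) and an input ratio of 1.18 (1.17 to 1.19). At siVRK1 pT120 regions ubK119 was lower after siVRK1, with a ratio of 0.768 (0.764 to 0.772), but with regions of any input read number included the ratio was 1.04. Outside input peaks these regions had a ubK119 ratio of 0.609 (0.605 to 0.614) and an input ratio of 0.876 (0.869 to 0.882). The inputs themselves had ratios of 1.11 (1.10 to 1.12) at VRK1 regions and 0.905 (0.900 to 0.910) at siVRK1 pT120 regions.

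**Figure D2:**
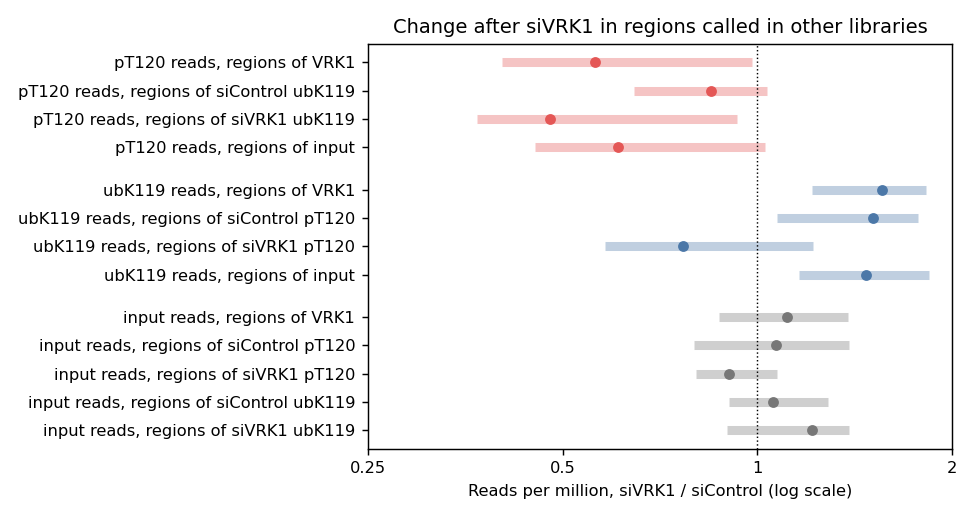
RPM in siVRK1 over siControl cells (log axis) for pT120 (red), ubK119 (blue) and input DNA (grey), in regions called in the library or libraries named on the y axis; points are ratios with their 95% counting intervals, mostly narrower than the points, and pale bars span the chromosomes. All 4 pT120 points lie below 1, from 0.478 to 0.847, and ubK119 lies above 1 except at siVRK1 pT120 regions (0.768).

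The deposited number of ubK119 peaks was lower after siVRK1, at 0.477 times that of siControl cells, but the siControl list started at 15 reads and the siVRK1 list at 18. At 18 reads and without thinning, 7651 siControl peaks stood against 13818, and at equal depth 1987 (1944 to 2026 over draws) against 13818, a ratio of 6.96. Outside input peaks, 441 siControl peaks at equal depth stood against 9814, a ratio of 22.2. The siControl heights had a median of 16 reads, below the minimum of 18, so thinning favoured this fall. The inputs had a ratio of 1.14 under the same treatment. Of the siControl ubK119 peaks 3787 (13.1%, 12.7 to 13.5) overlapped a siVRK1 peak, and circular shifts gave 0.441% and moves of 5 to 50 kb 6.63%. There were 25168 peaks in siControl cells only and 10071 in siVRK1 cells only. Input peaks of the siControl library overlapped those of the siVRK1 input in 27.3% (26.6 to 27.9) of cases.

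The 4 highest ubK119 peaks found after siVRK1 only, outside input peaks, were on chromosomes 19, 2 and 1. On chromosome 19 (46765107 to 46765846), 27 reads in siControl and 79 in siVRK1 cells gave an RPM ratio of 3.95 (2.52 to 6.36), while pT120 had 11 and 6 reads and the inputs 7 and 20 reads there. Over the input of the same siRNA, ubK119 stood at 2.56 (1.09 to 6.98) and 4.38 (2.66 to 7.56) times, with intervals that overlap. The peaks on chromosome 2 had ratios of 2.61 (1.8 to 3.83) from 15870988 to 15871780, where ubK119 stood at 2.14 (1.15 to 4.22) and 3.58 (2.30 to 5.73) times its inputs, and 3.54 (2.18 to 5.93) from 109831020 to 109831600. In the latter ubK119 stood at 0.798 (0.422 to 1.52) and 3.50 (2.08 to 6.10) times its inputs. The peak on chromosome 1 from 61800750 to 61801284 had a ratio of 4.60 (2.64 to 8.43), or 0.942 (0.424 to 2.16) and 5.85 (3.04 to 12.4) times its inputs. In these last regions the intervals did not overlap, although a choice among peaks found after siVRK1 only favours this direction. Of the 4 highest ubK119 peaks found in siControl cells only, that on chromosome Y (9971949 to 9972507) had the lowest ratio, 0.110 (0.0289 to 0.3004), with 49 and 4 reads. The ratios were 0.422 (0.242 to 0.706) on chromosome 21 (11148199 to 11149208) and 0.476 (0.225 to 0.943) on chromosome 15 (99700942 to 99701332). On chromosome 6 (133593882 to 133594330) the ratio of 0.712 had an interval (0.386 to 1.27) that includes 1, and the inputs had 5 and 13 reads. Over its own input, ubK119 went from 2.96 (1.52 to 6.32) to 0.403 (0.0937 to 1.36) times on chromosome Y, while in the other 3 regions the intervals of both siRNAs overlapped. The choice among peaks found in siControl cells only likewise favours lower levels after siVRK1.

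The longest peaks of the siVRK1 ubK119 list that lay outside input peaks and were found under both siRNAs were chosen after their values were seen. Being ranked in that list, they favour ubK119 in siVRK1 cells, and no direction is drawn for it. On chromosome 5, the region from 1552816 to 1556761 had 6.31 RPM of ubK119 in siControl and 17.98 RPM in siVRK1 cells, a ratio of 2.85 (2.45 to 3.32). The inputs had 2.05 and 3.46 RPM there, so that ubK119 stood at 3.08 and 5.20 times its inputs, while pT120 went from 4.88 to 1.22 RPM, a ratio of 0.2501 (0.171 to 0.360). On chromosome 11, the region from 44878724 to 44882653 had a ubK119 ratio of 2.43 (2.08 to 2.85), or 2.63 and 4.48 times its inputs, and a pT120 ratio of 0.301 (0.191 to 0.465). The siVRK1 ubK119 list had 70 regions of at least 1 kb outside input peaks with at most 100 reads in each input. In these, pT120 stood at 1.54 times its input in siControl and 0.339 times in siVRK1 cells. In the 45 such regions of the siControl ubK119 list, pT120 stood at 1.304 and 0.740 times. The siControl excess depended on the input used. In the 70 regions siControl pT120 was 89.5 RPM, against 58.2 RPM in the siControl and 86.6 RPM in the siVRK1 input. In the 45 regions it was 46.7 RPM, against 35.8 and 44.9 RPM.

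The siControl lists were then set side by side to see whether VRK1, pT120 and ubK119 occupied the same regions. Of the 17531 VRK1 peaks, 2841 (16.2%, 15.7 to 16.8) overlapped a pT120 peak and 3992 (22.8%, 22.2 to 23.4) a ubK119 peak. Of the 6665 pT120 peaks, 2800 (42.0%, 40.8 to 43.2) overlapped a ubK119 peak. Circular shifts gave 0.322%, 0.974% and 1.17%, so the overlaps were 50.4, 23.4 and 35.8 times chance. With moves of 5 to 50 kb, which keep the local copy number, they were 2.34, 1.82 and 2.02 times chance. Outside input peaks, 259 of 11489 VRK1 peaks (2.25%) overlapped a pT120 peak, 6.49 times the level of such moves, and 702 (6.11%) overlapped a ubK119 peak, 2.24 times that level.

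The highest peaks outside input peaks were shared by the antibodies. The 5 highest peaks of each antibody library fell on 9 distinct regions, and 24 of these 25 peaks lay in regions called in all 5 antibody libraries. Such sharing was rare in the whole lists: outside input peaks, 30 of 3050 siControl pT120, 29 of 37994 siVRK1 pT120, 29 of 11489 VRK1, 33 of 23695 siControl ubK119 and 28 of 9814 siVRK1 ubK119 peaks were common to all 5. The inputs had at most 11 reads in each of the 9 regions, and the ratios there are not scaled to them. Over input, the intervals of both siRNAs overlapped for pT120 in all 9 regions, and for ubK119 in all but that on chromosome 1. Such overlap leaves a difference relative to input undecided. The region on chromosome 1 from 205204806 to 205205198 had 155 VRK1 reads, 4.84 RPM against 0.335 RPM in the siControl input. There pT120 went from 5.37 RPM in siControl to 1.33 RPM in siVRK1 cells, a ratio of 0.248 (0.173 to 0.351), and ubK119 from 1.81 to 5.80 RPM, a ratio of 3.22 (2.43 to 4.29). On chromosome 16 (3124472 to 3124876) VRK1 reached 4.31 RPM, and the ratios were 0.274 (0.194 to 0.384) for pT120 and 2.66 (1.99 to 3.59) for ubK119. On chromosome 12 (127861063 to 127861423) VRK1 reached 3.68 RPM, with ratios of 0.213 (0.146 to 0.304) and 2.84 (2.06 to 3.93). The region on chromosome 2 from 232544235 to 232544632 had ratios of 0.228 (0.134 to 0.375) and 3.22 (2.005 to 5.30). On chromosome 4 (178071083 to 178071476) they were 0.239 (0.134 to 0.411) and 2.30 (1.40 to 3.85). The region on chromosome 10 from 28944471 to 28944693 stood apart, with 1.305 and 1.304 RPM of pT120 and a ubK119 ratio of 1.26 (0.887 to 1.78). On chromosome 21 (20161071 to 20161288) the pT120 ratio of 1.34 (0.755 to 2.47) was likewise within counting error of 1. On chromosome 18 (45900066 to 45900444) the pT120 ratio was 0.474 (0.244 to 0.910) and the ubK119 ratio 1.38 (0.890 to 2.14). The ninth region, on chromosome 3 from 84163786 to 84164138, was called in 4 antibody libraries and is the first of the siControl-only pT120 peaks above, with a ubK119 ratio of 2.21 (1.26 to 3.94). Outside these 9, the sixth highest VRK1 peak with pT120, on chromosome 2 from 177127132 to 177127524, had ratios of 0.241 (0.116 to 0.474) for pT120 and 4.27 (2.48 to 7.71) for ubK119. With 5 and 3 input reads there, pT120 stood at 8.06 (3.11 to 26.6) and 4 (1.10 to 21.9) times its inputs, with overlapping intervals.

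**Figure D3:**
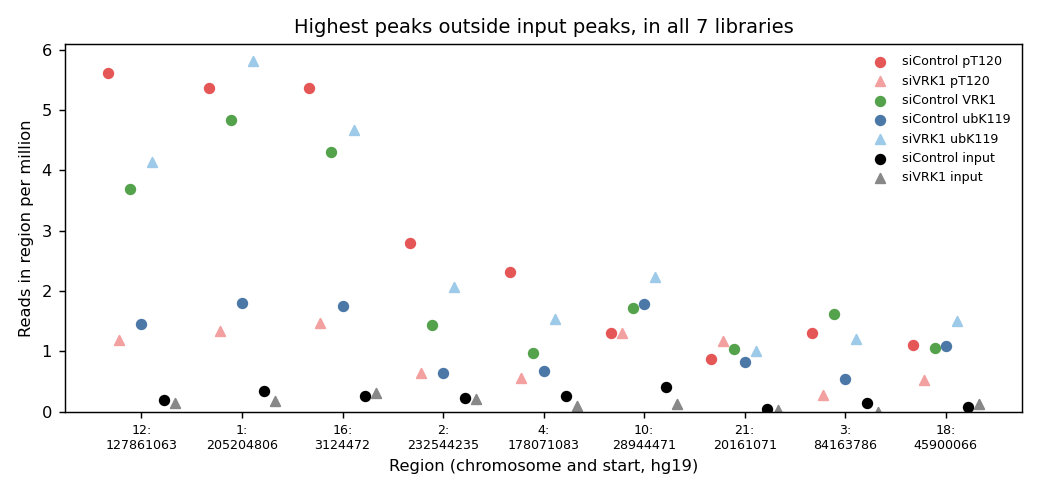
RPM in the 9 regions that hold the 5 highest peaks outside input peaks of each antibody library; circles are siControl and triangles siVRK1 libraries, 1 point per library, and the x axis gives chromosome and start in hg19. In the regions of chromosomes 12, 1 and 16 siControl pT120 lies between 5.37 and 5.61 RPM and siVRK1 pT120 between 1.19 and 1.47 RPM.

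The marks were also compared with each other, to see whether ubK119 appeared where pT120 was no longer called after siVRK1. Of the 4045 pT120 peaks found in siControl cells only, 7.81% (7.003 to 8.68) overlapped a ubK119 peak in siVRK1 cells only and 5.54% (4.85 to 6.29) one in siControl cells only. Of the 2620 pT120 peaks shared by both siRNAs, 4.31% (3.57 to 5.16) had ubK119 in siVRK1 cells only and 23.2% (21.6 to 24.8) in siControl cells only, and 62.1% had it under both. Among the 40011 pT120 peaks found after siVRK1 only, the shares were 0.332% (0.278 to 0.394) and 5.27% (5.05 to 5.49). Input peaks of siControl cells without pT120 had ubK119 in siVRK1 cells only in 2.62% (2.36 to 2.91) of 13604 cases. For the siControl-only pT120 peaks, all 1000 circular shifts gave a lower share, 0.267% on average, and moves of 5 to 50 kb gave 2.19%. The input peaks without pT120 likewise exceeded all 1000 circular shifts, 0.242% on average, and moves gave 0.783%. Outside input peaks the share was 3.63% (2.98 to 4.38), and moves gave 1.245%, while 3.22% (2.60 to 3.93) had ubK119 in siControl cells only. The ubK119 lists differ in length and height minimum, so shares under the siRNAs are not set against each other. Most of the 4045 peaks, 78.2%, had no ubK119 peak under either siRNA.

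Peaks were concentrated on a few chromosome parts in all libraries, the inputs included. The part of the short arm of chromosome 18 from 5 to 15 Mb held 22.1% of siControl pT120 peaks, 7.52% of siVRK1 pT120 peaks and 12.6% of VRK1 peaks, against 13.9% and 11.04% of the siControl and siVRK1 input peaks. For ubK119 the shares were 10.8% and 8.39%. Chromosome 18 as a whole had 19.1 siControl pT120 peaks per Mb and 41.9 after siVRK1, 28.9 VRK1 peaks per Mb, and 32.7 and 31.0 input peaks per Mb. Chromosome 3 held 11.3% of pT120 peaks in siControl and 25.5% in siVRK1 cells, against 19.5% and 17.8% of input peaks. On chromosome 5, the first 5 Mb held 1296 siControl and 768 siVRK1 ubK119 peaks, 4.48% and 5.56% of their lists, against 0.890% and 1.83% of the input lists. Chromosome X, by contrast, had 0.415 to 0.758 peaks per Mb over the 7 libraries. It was not alone in this: chromosome 15 had 0.176 siControl pT120 peaks per Mb against 0.443 on chromosome X. After siVRK1 the pT120 values were 1.06 and 0.758.

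**Figure D4:**
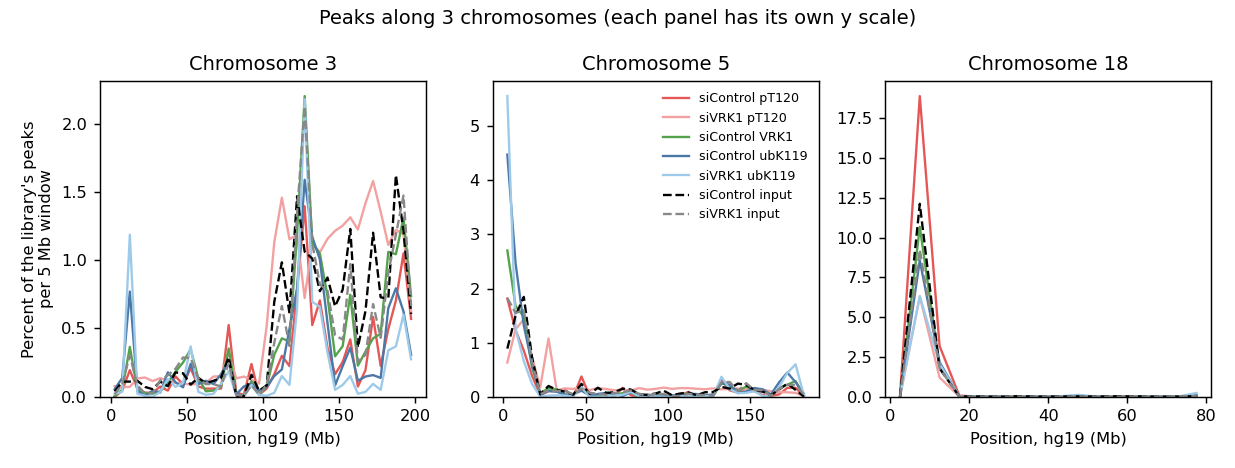
Percent of the peaks of each library in windows of 5 Mb along chromosomes 3, 5 and 18 (hg19), with a y scale of its own in each panel; solid lines are antibody libraries and dashed lines inputs. The window from 5 to 10 Mb of chromosome 18 holds 18.9% of siControl pT120 peaks and 12.1% of siControl input peaks, and ubK119 exceeds the inputs in the first window of chromosome 5.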

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

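The tests in this part were chosen after the results were seen, except the correlations across 5 Mb windows. The marks differed in their direction after siVRK1 in both readouts: peak numbers were 6.37 times those of siControl for pT120 and 0.477 times for ubK119, and RPM at VRK1 regions had ratios of 0.562 and 1.56. With 1 library each, the difference between the marks was not tested.

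For the peak numbers, depth and the height minimum were weighed. At equal depth and minimum the ratio was 0.349 for pT120 and 6.96 for ubK119. Thinning lowered the heights of the deeper list only. Their median was 12 reads for siVRK1 pT120 and 16 for siControl ubK119, against minimums of 12 and 18. A large loss was thus built in, and these ratios do not show that depth was the cause. At 18 reads without thinning, 7651 siControl ubK119 peaks stood against 13818, so that deficit was gone without it. The deposited numbers may reflect depth for pT120, and depth with the minimum of each list for ubK119. Their direction was not that of the reads. The effect of VRK1 on the number of sites stays open.

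For the opposite RPM ratios, the tables argue against the coverage trend of the input DNA as the whole cause, if each precipitate shared the trend of its input. At VRK1 regions the input ratio was 1.11 (1.10 to 1.12), on the other side of 1 from that of pT120. Division by it could thus only move pT120 further from 1, to 0.505 (0.5004 to 0.5103). For ubK119 the division left 1.40 (1.39 to 1.42). Different amounts of input-like, non-specific DNA as the whole cause cannot be told apart. They would not move a level past that of the input. At VRK1 regions pT120 went from 1.06 (1.0499 to 1.065) to 0.534 (0.531 to 0.538) times its inputs, and ubK119 from 0.804 (0.799 to 0.809) to 1.13 (1.12 to 1.13) times. The siControl pT120 level of 6622 RPM, however, lay between the inputs (6262 and 6959 RPM), so its side depended on the input used. The ubK119 levels, 5034 and 7850 RPM, lay below and above both inputs. The stretch of chromosome 1 that resembles mitochondrial DNA went with the explanation for both marks, with ratios of 1.57 (1.41 to 1.75) and 0.544 (0.489 to 0.605). The tables further argue against a difference of the same size at all regions for pT120 outside input peaks, where the log2 ratio at VRK1 regions differed from that at input regions by -0.39 (-0.41 to -0.38), whereas for ubK119 this cannot be told apart, as 0.22 (0.21 to 0.24) became 0.072 (0.050 to 0.094) after division by the input ratios. A difference between libraries not tied to VRK1 sites stays open, with -0.12 (-0.13 to -0.10) and 0.085 (0.074 to 0.096) for all VRK1 regions, while an action of VRK1 at its sites cannot be told apart, since outside input peaks the pT120 log2 ratio at VRK1 regions lay 0.29 above regions without a VRK1 peak of the siVRK1 ubK119 list and -0.96 from those of the siControl list, and that of ubK119 lay 0.057 and 1.52 above those of the siControl and siVRK1 pT120 lists. Coverage trends such as base composition that differ by library cannot be told apart either. Across 308 windows the input ratio had a Spearman rho of -0.559 with the pT120 ratio and 0.384 with the ubK119 ratio. The ratios of the marks had a rho of -0.638 with each other. Both values for the input met the bound of 0.3 set beforehand on the size of rho. A bound on size alone decides nothing where the signs are opposite.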

How the results depend on the processing

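Of the alternatives run, 27 left the value within its counting interval, within 1.5 times the main count or, for named peaks, above the input, 85 moved it without a change of direction and 7 reversed it. The named peaks were chosen for their height outside input peaks, so their place above the input was favoured by that choice. No paired analysis was possible because each condition had 1 library, and no library could be left out. Promoter windows, genes with a promoter peak, gene lists and random lists were planned and not run for lack of an annotation of the same build. Alternatives on depth, local moves, RPM, regions outside input peaks and chromosomes left out were chosen after seeing the data. Except where said, the cause was not tested.

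Peaks above the median height of their list, fewer by construction, numbered 2772 siControl and 20570 siVRK1 pT120 peaks, 6661 VRK1 peaks, 11404 and 5183 ubK119 peaks, and 5964 and 8022 input peaks. Without input peaks, 3050 siControl pT120 and 11489 VRK1 peaks were left. The ratio of peak numbers reversed at equal depth and height minimum to 0.349 for pT120 and 6.96 for ubK119, and at equal height in RPM to 0.233 for pT120, 9.05 for ubK119 and 0.703 for the inputs. For pT120 the height minimum was already common, so thinning alone reversed the ratio at equal depth. As thinning acts on the deeper list only, that reversal was favoured by the method.

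With 0.5 of the shorter peak required, the shared share was 33.5% for pT120 and 10.5% for ubK119 between siRNAs, 14.9% for VRK1 with pT120, 19.6% for VRK1 with ubK119 and 36.8% for pT120 with ubK119. With input peaks it was 21.2% for VRK1, 40.3% and 7.03% for siControl and siVRK1 pT120, and 11.96% and 24.2% for siControl and siVRK1 ubK119. Above the median height the shares were 66.4%, 19.7%, 28.4%, 38.6% and 66.7% in the order of the first 5, and outside input peaks 3.87%, 4.95%, 2.25%, 6.11% and 6.07%. With the same number of top peaks, they were 33.3% for pT120 and 21.8% for ubK119 between siRNAs. Moves of 5 to 50 kb lowered the fold over chance to 1.66 for pT120 and 1.97 for ubK119 between siRNAs, and to 2.34, 1.82 and 2.02 for VRK1 with pT120, VRK1 with ubK119 and pT120 with ubK119. The share of siControl-only pT120 peaks with ubK119 in siVRK1 cells only was 3.63% outside input peaks.

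The RPM ratios at VRK1 regions, scaled to input regions, were 0.922 for pT120 and 1.06 for ubK119. With regions of any input read number they were 0.704 and 1.45 at VRK1 regions, and 0.704 and 1.43 at input regions. As medians over regions they were 0.486 and 1.64, and 0.574 and 1.49 at input regions. Without chromosome 18 they were 0.537 and 1.64, and 0.576 and 1.54 at input regions. Without chromosomes 3, 5 and 18, ubK119 had 1.61 at VRK1 regions, and at input regions the values were 0.582 and 1.54. Outside input peaks they were 0.463 and 1.71 at VRK1 regions. Divided by the input ratio they were 0.505 and 1.40, and 0.572 and 1.38 at input regions. For pT120 at siControl ubK119 regions the scaling to input regions reversed the ratio to 1.39, and for ubK119 at siVRK1 pT120 regions the inclusion of any input read number reversed it to 1.04.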

Other observations

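Beside the first 5 Mb of chromosome 5, several windows held a larger share of ubK119 peaks than of input peaks under both siRNAs, chosen after their values were seen. From 40 to 45 Mb of chromosome 11 the share was 6.58 times that of its own input in siControl and 5.45 times in siVRK1 cells, from 130 to 135 Mb of chromosome 10 it was 6.34 and 6.19 times, and from 10 to 15 Mb of chromosome 3 it was 6.92 and 3.93 times. VRK1 stood at 1.95, 2.32 and 3.28 times in these windows. For pT120 the values were 1.89, 1.17 and 1.75 times in siControl cells and 1.01, 0.132 and 0.242 times in siVRK1 cells. From 140 to 145 Mb of chromosome 8, ubK119 stood at 3.41 and 6.54 times. These values depend on the input used. Against the mean of both inputs, ubK119 was higher in siVRK1 cells in all 4 windows, so no direction between the siRNAs is drawn for the first 3 of them. In those 3, VRK1 then stood at 1.67, 1.74 and 1.77 times and siControl pT120 at 1.62, 0.878 and 0.943 times, so the latter is not called above input on chromosomes 10 and 3.

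Very high regions were present in every library. On chromosome 1, next to the centromere, the region from 121483973 to 121485649 had 1958 and 1576 RPM in the siControl and siVRK1 inputs and between 1287 and 1595 RPM in the antibody libraries. Near the centromere of chromosome 8, the region from 43092681 to 43095472 went against the general direction, with a pT120 ratio of 3.55 (3.30 to 3.82) and a ubK119 ratio of 0.285 (0.258 to 0.314), while the input ratio was 0.885 (0.830 to 0.945). The stretch of chromosome 1 from 564447 to 570485, which resembles mitochondrial DNA, had 71.7 and 71.9 RPM in the inputs. The antibody libraries held less of it than their inputs, at 12.7% for VRK1, 31.7% and 49.5% for siControl and siVRK1 pT120, and 41.5% and 22.5% for siControl and siVRK1 ubK119.

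The sharing of the highest peaks by all antibodies was tested after it was seen, at the 20 highest VRK1 sites outside input peaks. Recovery that does not depend on the antibody cannot be told apart, since 7 of these sites were among the shared regions that prompted the test, and the lowest of the medians over input in the other 4 antibody libraries, 2.60 (siControl ubK119), restates the sharing. Phosphorylation by VRK1 at these sites cannot be told apart either, since the pT120 log2 ratio differed from that at input regions by -0.86 (-1.03 to -0.69), but after division by the input ratios by -0.32 (-0.73 to 0.085). The RPM ratio there was 0.336 (0.299 to 0.377) for pT120, 2.09 (1.90 to 2.31) for ubK119 and 0.735 (0.568 to 0.949) for the inputs. A control precipitation without a specific antibody, not analysed here, could separate the explanations.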
